A study of Homo sapiens with 12 samples.

How the data were processed

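RNA abundance was measured by sequencing in MIA PaCa-2 cells, an established line from a human pancreatic carcinoma. Lentiviral short hairpin RNAs (shRNAs) against MSI1 (Musashi-1, virus marked with GFP) or MSI2 (Musashi-2, virus marked with Tomato Red), or a scrambled control shRNA, were delivered 72 hours before cells were sorted on their fluorescence. The double-knockdown cells were the double-positive ones. Libraries were made from 200 ng of total RNA by standard Illumina protocols, per the labels' protocols. The tag and the sorting gate of the control cells, and whether library preparation kept strand information, are not given in the sources used here. There were 12 libraries in 4 groups of 3: control shRNA, Msi1 knockdown, Msi2 knockdown and double knockdown. The groups were taken from the sample titles.

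The deposited values were estimated counts per gene, given as whole numbers and not scaled between libraries. Kallisto 0.42.1, CASAVA 1.4 and the build hg19 are named in the submitters' processing notes, without their roles. The transcript set, the way transcripts were summed to genes and any filter are not given in the sources used here. Kallisto assigns reads that several transcripts share by a likelihood model, so values of near-identical genes depend on that split. The table held 24528 genes, each with a numeric gene ID, a symbol and a description. Of these, 20993 had a count in at least 1 library. There was no entry without a gene name and no column that was not used. The table held no coordinates, and the reference at hand was of another build, so no coordinates are printed.

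Genes were tested with edgeR 4.0.16 in R 4.3.3. Counts were used as deposited, with no further rounding. The low-count filter filterByExpr (minimum count 10) by group left 15021 genes. Libraries were scaled with TMM factors, and all 12 libraries entered 1 model with a mean per group and 8 residual degrees of freedom. The robust quasi-likelihood fit gave a test for each gene, with p-values adjusted over all tested genes by the Benjamini-Hochberg method at a threshold of 0.05. Tests were two-sided. Standard errors of log2 changes were the change divided by the square root of its F statistic. CPM values are counts per 1e6 of the TMM-scaled library total, given as mean ± SD over the 3 libraries of a group. For 3 libraries against 3, an exact permutation test cannot go below p = 0.1, so tests of single genes rest on the model fitted across all genes.

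There were 7 comparisons: each of the 3 knockdowns against control, the 3 knockdowns against each other, and the non-additivity of the double knockdown. Non-additivity is the log2 change in the double knockdown minus the sum of the log2 changes in the single knockdowns, all against control.

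The comparisons, the alternative settings, the gene lists and the rule for named genes were fixed before the data were examined. Named genes were MSI1, MSI2, MET and HMGA2 in each comparison with control. They were joined by the 6 largest rises and 6 largest falls among genes with an adjusted p below the threshold, a mean of at least 10 CPM in the higher group and no overlap between the libraries of the compared groups. Chance alone leaves no overlap for 10% of genes with 3 libraries against 3. In the other 4 comparisons the 3 largest rises and 3 largest falls were taken. For each list, up to 3 members with the smallest p were available to name. Genes named outside this rule are said to be so. Some genes that the rule picked are not reported here.

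The 32 gene lists covered cell cycle phases, stress and signalling responses, lipid and energy metabolism, ribosomes, epithelial and mesenchymal genes, Musashi-linked and stem cell genes, and markers of other cell types (fibroblasts, endothelium, blood, pancreatic acinar and ductal cells, and neuronal genes expressed in virus packaging cells). Symbols were matched to the table through current and older names, and 748 of the listed entries (99.9%) matched. Each list was tested with camera in limma 3.58.1 with the preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Fry tests whether the members of a list move, on balance, one way, and does not compare the list with other genes. DESeq2 was not run for the lists.

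Transcript lengths came from GENCODE 29, the longest transcript of each gene, and 99.3% of the tested genes had one. Within-group structure was measured on genes above 3 log2 CPM, with 2 counts added before taking logs. Deviations from the group means gave a first component, and each library's score on it is called the library trend. Values of library measures were compared by exact permutation over the 220 ways to choose 3 of 12 libraries.

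The scripts were tested on simulated data, counts drawn from the means and spread of these libraries with 50 genes changed at each fold size and 14817 genes tested. In the simulated Msi1 comparison, 44.0% of 1.25-fold, 90.0% of 1.5-fold, 96.0% of 2-fold and 100.0% of 4-fold changes were recovered, and 6.67% of the calls were false. In the simulated Msi2 comparison the shares were 50.0%, 94.0%, 100.0% and 100.0%, with 9.95% false calls. In the simulated double-knockdown comparison they were 38.0%, 90.0%, 100.0% and 100.0%, with 7.87% false calls. All 3 set tests called the planted list and 0 of 30 unchanged lists in the simulation. Simulated genes were drawn independently of each other, so this does not show how often the set tests call unchanged lists of correlated genes. These simulated libraries also held no library trend and far fewer changed genes than were called in the data. The shares of recovered and false calls therefore need not hold for the real gene counts.

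The alternatives set in advance were DESeq2 1.42.0 in place of edgeR, median-of-ratios size factors in place of TMM, no low-count filter, a stricter filter of 5 CPM in 3 libraries, only the compared groups in the model, the replicate number as a block, the 2 other set tests, and each library left out in turn. Chosen after seeing the data were the library trend as a covariate, a correction for transcript length, thinning of all libraries to the total of the smallest, and leaving out mitochondrially encoded genes. Another 4 gene lists were also added after the values were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.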

Results

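Gene expression was measured by RNA sequencing in 12 libraries of sorted MIA PaCa-2 cells, a pancreatic carcinoma line. Each of 4 groups had 3 libraries: control shRNA, Msi1 knockdown, Msi2 knockdown and double knockdown. MSI1 and MSI2 encode the Musashi proteins, related RNA-binding proteins that act on the stability and translation of target mRNAs. Total estimated counts, in units of 1e6, ran from 10.9 to 35.04 in the control libraries, 26.8 to 38.9 in the Msi1 knockdown, 39.7 to 53.01 in the Msi2 knockdown and 39.9 to 56.1 in the double knockdown. Of 15021 genes tested, levels are given as counts per 1e6 (CPM, mean ± SD, n = 3) and changes as log2 values ± standard error from edgeR. Replicates were not stated to be separate cultures, so p-values measure only the spread between these samples, which may be technical. All pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 3.83 to 36.2.

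The libraries also differed along a trend that was present within groups and that held 53.9% of the within-group variance. Scores on this trend ran from -1.54 to -1.06 in the double-knockdown libraries and from -0.39 to 1.38 in the other 9 (exact permutation p = 0.00455, two-sided, the smallest that 220 splits can give; 0.0182 adjusted over 8 tests). The Msi1 knockdown lay toward the other end, with a mean score of 0.95, against 0.03 in control and 0.33 in the Msi2 knockdown. Msi1 knockdown replicates 2 and 3 scored 1.37 and 1.38, and the highest control library 0.68. Genes of long transcripts scored high on the trend (Spearman's rho = 0.41 across genes, which are not independent replicates). The slope of log2 level on log2 transcript length averaged -0.10 in the double knockdown and 0.03 in the other libraries, with the same exact permutation p of 0.00455. Mitochondrially encoded genes took 5.68% of counts in the double knockdown and 6.82% in the other libraries (exact permutation p = 0.05, adjusted 0.1). The control libraries lay apart in the slope of log2 level on GC content of the longest transcript. Per 10 percentage points it ran from -0.058 to -0.023 in control and from -0.013 to 0.086 in the knockdown libraries. This difference was not tested. Spearman's rho of log2 changes with GC content was 0.11, 0.13 and 0.17 in the Msi1, Msi2 and double knockdown against control.

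**Figure D1:**
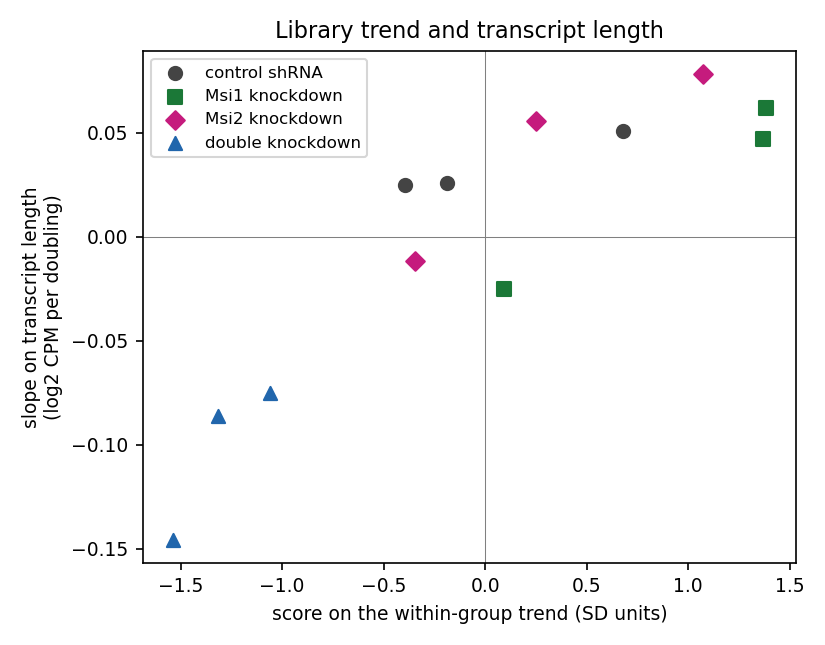
Score of each of the 12 libraries on the first component of the within-group deviations, against the slope of log2 level on log2 transcript length, coloured by group. The 3 double-knockdown libraries lie between -1.54 and -1.06, below all other libraries.

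The targeted transcripts fell in the cells given their shRNAs. MSI1 (gene ID 4440) stood at 4.53 ± 0.40 CPM in control cells, 1.84 ± 0.19 CPM in the Msi1 knockdown and 1.71 ± 0.28 CPM in the double knockdown. Its log2 changes were -1.33 ± 0.16 and -1.42 ± 0.15 (edgeR adjusted p = 1.5e-06 and 3.7e-07), and each library of these 2 groups lay below each control library. MSI2 (gene ID 124540) stood at 82.7 ± 3.1 CPM in control cells, 14.97 ± 2.4 CPM in the Msi2 knockdown and 11.8 ± 0.6 CPM in the double knockdown. Its log2 changes were -2.46 ± 0.09 and -2.81 ± 0.09 (edgeR adjusted p = 3.8e-13 and 4.9e-14). MSI1 was a low transcript, with 46 to 309 counts per library in the control and Msi2 knockdown groups.

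The related transcript moved too. In the Msi1 knockdown MSI2 stood at 54.0 ± 2.3 CPM, a log2 change of -0.61 ± 0.08 (edgeR adjusted p = 6.8e-06). In the Msi2 knockdown MSI1 stood at 6.14 ± 0.82 CPM, a log2 change of 0.41 ± 0.13 (edgeR adjusted p = 0.0244). This rise no longer passed without control replicate 2 (adjusted p = 0.0796), control replicate 3 (0.0717) or Msi2 knockdown replicate 1 (0.121). MSI2 was 0.35 lower on the log2 scale in the double than in the Msi2 knockdown (a change of -0.35; edgeR adjusted p = 0.0041), whereas the difference of MSI1 between the double and the Msi1 knockdown was -0.09 (adjusted p = 0.651).

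**Figure D2:**
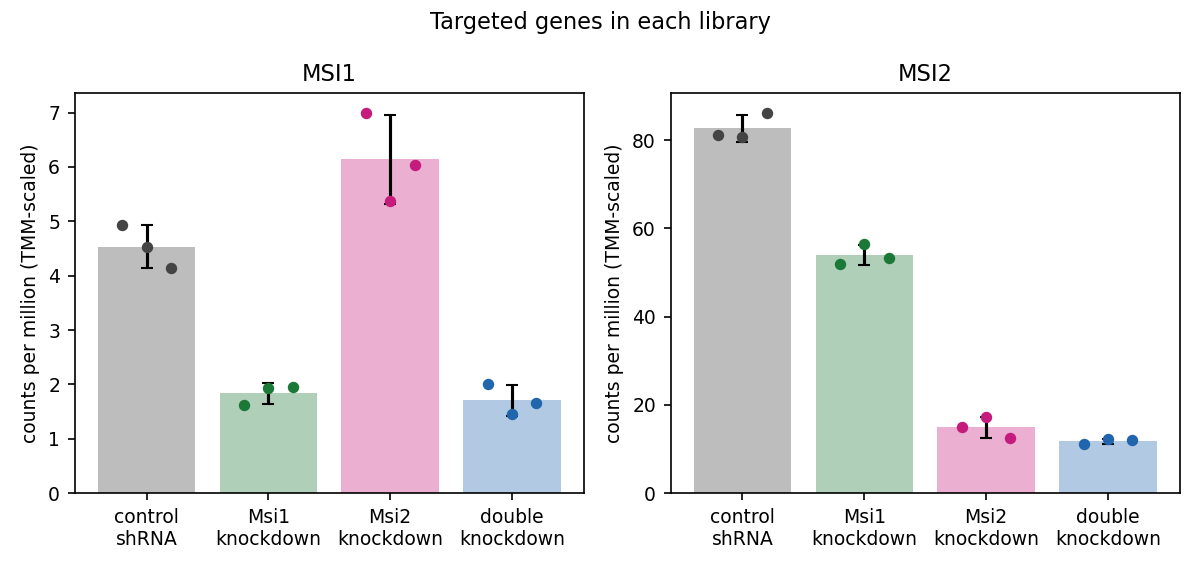
MSI1 and MSI2 in CPM in each of the 12 libraries, with group means and SD bars. MSI1 was 4.53 CPM in control and 1.84 CPM in the Msi1 knockdown, and MSI2 was 82.7 CPM in control and 14.97 CPM in the Msi2 knockdown.

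MET and HMGA2, a receptor tyrosine kinase and a chromatin architectural protein of the Musashi-linked list, were followed in each knockdown. MET stood at 41.5 ± 1.2 CPM in control cells. It fell in the Msi1 knockdown (log2 -0.52 ± 0.07, edgeR adjusted p = 1.4e-05) and in the double knockdown (-0.70 ± 0.07, adjusted p = 2.6e-07). In the Msi2 knockdown its change was -0.22 ± 0.07 (adjusted p = 0.0267), a call lost without control replicate 1 (0.0858), control replicate 3 (0.0684), Msi2 knockdown replicate 1 (0.0604) or Msi2 knockdown replicate 2 (0.0707).

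HMGA2 was near 1 CPM in control cells (0.97 ± 0.33 CPM), and only its change in the double knockdown, -0.70 ± 0.28, passed among the 3 comparisons with control (edgeR adjusted p = 0.0437). That call was lost with DESeq2 (adjusted p = 0.0817), without control replicate 2 (log2 -0.38, adjusted p = 0.359), without double knockdown replicate 1 (0.167) and without double knockdown replicate 3 (0.0935). It was also lost with thinned libraries (log2 -0.45, edgeR adjusted p = 0.361) and with the length correction (-0.56, 0.0952). With the library trend as a covariate the HMGA2 change was -0.18 (adjusted p = 0.735) in the double and -0.64 (adjusted p = 0.0385) in the Msi2 knockdown.

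The first comparison asked what the Msi1 shRNA changed. The Msi1 knockdown raised VGF, a neuropeptide precursor, from 10.6 ± 1.5 to 60.6 ± 6.0 CPM (log2 2.52 ± 0.10, 5.75-fold) and CD274, which encodes the immune checkpoint ligand PD-L1, from 2.60 ± 0.33 to 12.98 ± 1.6 CPM (log2 2.37 ± 0.13). SPOCD1 rose from 4.67 ± 1.21 to 31.0 ± 3.0 CPM (log2 2.64 ± 0.14). CDH5, the cadherin of endothelial junctions, the immediate early transcription factor EGR3 and the secreted glycoprotein STC1 rose by log2 2.26 ± 0.10, 2.21 ± 0.09 and 1.86 ± 0.12. PRODH, the mitochondrial enzyme that begins proline breakdown, fell from 19.7 ± 1.8 to 2.95 ± 0.18 CPM (log2 -2.76 ± 0.11). TXNDC5, a disulfide isomerase of the endoplasmic reticulum, fell from 298 ± 22 to 84.7 ± 13.8 CPM (log2 -1.82 ± 0.10), and NSF, the ATPase that takes apart SNARE complexes, from 86.5 ± 8.4 to 28.7 ± 2.1 CPM (log2 -1.60 ± 0.08). C7orf60, TP53INP1 and ABAT, the GABA transaminase, fell too, with log2 changes of -1.99 ± 0.13, -1.75 ± 0.10 and -1.74 ± 0.16. The largest edgeR adjusted p of these 12 genes was 4.9e-08. In all, 2772 genes were higher and 3135 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 261 and 171 of them by 2-fold or more (101 and 57 under the stricter filter). DESeq2 called 2745 higher and 2920 lower.

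Genes of inflammatory signalling rose together in the Msi1 knockdown. Of 19 measured genes of the NF-kB and inflammatory cytokines list, 14 rose, 0 fell and 5 did not pass, and 14 rose when adjusted over the list alone (median log2 0.64, camera adjusted p = 6.1e-12; adjusted p = 0.0588 with an estimated correlation). Among them were TNFAIP3, a feedback inhibitor of NF-kB (1.24 ± 0.08), the chemokine CXCL8 (83.2 ± 8.3 to 183 ± 6 CPM, log2 1.14 ± 0.08) and BIRC3 (0.87 ± 0.07). Of 25 TGF-beta targets and matrix genes, 14 rose, 3 fell and 8 did not pass (14 and 4 adjusted over the list alone; camera adjusted p = 1.5e-06; adjusted p = 0.467 with an estimated correlation). The metalloproteinase inhibitor TIMP1 rose by 1.03 ± 0.08 and CYR61 by 1.03 ± 0.08. The TGF-beta median was 0.47, and 0.24 with the library trend as a covariate. Of 17 immediate early genes, 12 rose, 3 fell and 2 did not pass (12 and 3 adjusted over the list alone; camera adjusted p = 1.6e-05; adjusted p = 0.467 with an estimated correlation), with EGR1 at 0.93 ± 0.07 and IER3 at 1.26 ± 0.10. Of 22 endoplasmic reticulum chaperones, 14 rose, 0 fell and 8 did not pass (14 and 0 adjusted over the list alone; camera adjusted p = 8.3e-08; adjusted p = 0.531 with an estimated correlation). HYOU1 rose by 0.98 ± 0.08, PDIA6 by 0.70 ± 0.08 and the transcription factor XBP1 by 0.61 ± 0.07.

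Lipid synthesis genes fell in the Msi1 knockdown. Of 22 cholesterol synthesis genes, 13 fell, 3 rose and 6 did not pass (13 and 3 adjusted over the list alone; median -0.24, camera adjusted p = 0.0053; adjusted p = 0.531 with an estimated correlation). Lanosterol synthase LSS fell by 0.70 ± 0.07, HMGCS1 by 0.59 ± 0.06 and IDI1 by 0.74 ± 0.08 on the log2 scale. Of 14 fatty acid synthesis genes, 8 fell, 3 rose and 3 did not pass (8 and 3 adjusted over the list alone; camera adjusted p = 0.0018; adjusted p = 0.467 with an estimated correlation). ACLY, the ATP citrate lyase that makes cytosolic acetyl-CoA, went from 518 ± 20 to 221 ± 6 CPM (log2 -1.23 ± 0.06), and the acetyl-CoA synthetase ACSS2 fell by 0.69 ± 0.06. Of 16 heat shock chaperones, 8 fell, 1 rose and 7 did not pass (10 and 1 adjusted over the list alone; camera adjusted p = 0.0423; adjusted p = 0.795 with an estimated correlation). HSPA1A and HSPA1B, near-identical genes whose reads cannot be split with certainty, had log2 changes of -0.83 ± 0.12 and -0.77 ± 0.10. The heat shock call was lost without control replicate 3 (adjusted p = 0.0781), Msi1 knockdown replicate 2 (0.116) or Msi1 knockdown replicate 3 (0.126), under the stricter filter (0.089) and with the library trend as a covariate (0.615).

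The other 25 lists were not called in the Msi1 knockdown. Members of the p53 targets list went both ways, with 8 of 24 higher and 13 lower, among them the cell cycle inhibitor CDKN1A (1.20 ± 0.10) and BTG2 (-0.83 ± 0.08). So did the type I interferon response (8 higher and 10 lower of 34), hypoxia and glycolysis (9 and 7 of 30), ATF4 and integrated stress response (8 and 8 of 24), chromatin regulators (6 and 9 of 26) and Musashi-linked genes (4 and 5 of 13). G2/M and mitosis had 2 higher and 10 lower of 38, S phase and DNA replication 6 and 6 of 40, ribosomal proteins 0 and 2 of 43 and replication-dependent histones 0 and 4 of 11. Nuclear genes of oxidative phosphorylation had 3 higher and 3 lower of 35, mitochondrially encoded genes 1 and 0 of 13, ribosome biogenesis and MYC targets 10 and 4 of 31, Notch pathway 6 and 2 of 18, WNT pathway 3 and 3 of 16, MAPK output 10 and 6 of 21 and apoptosis regulators 11 and 6 of 28. Among epithelial genes (6 higher and 4 lower of 18) the tight junction gene CLDN1 rose by 1.46 ± 0.08, and among mesenchymal and EMT genes (4 and 2 of 13) the membrane-bound metalloproteinase MMP14 rose by 1.72 ± 0.15. Nestin (NES) rose by 1.59 ± 0.09 in the stem cell and drug resistance list (6 higher and 4 lower of 16). Ribosomal proteins (median -0.05, camera adjusted p = 0.397) were called lower without Msi1 knockdown replicate 1 (-0.14, adjusted p = 0.0115) and higher with the library trend as a covariate (0.12, adjusted p = 0.0291). With that covariate MAPK output (adjusted p = 0.0291) and apoptosis regulators (0.00944) were called higher as well.

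Markers of other cell types were not called by camera in any knockdown. In the Msi1 knockdown, 3 of 10 fibroblast markers were higher and 1 lower, 1 of 6 endothelial markers was higher (CDH5) and 1 lower, 2 of 8 blood cell markers were higher and 0 lower, 2 of 7 pancreatic acinar and ductal markers were higher and 0 lower, and 1 of 5 neuronal genes of packaging cells was higher and 2 lower. In the Msi2 knockdown the counts were 3 and 1, 1 and 0, 1 and 0, 1 and 2, and 1 and 2, in the same order. In the double knockdown they were 3 and 3, 1 and 2, 1 and 0, 2 and 1, and 1 and 3. Fry, which does not set a list against other genes, called the fibroblast (adjusted p = 0.0221), endothelial (6.6e-04), blood cell (0.00136) and pancreatic markers (0.00133) higher in the Msi1 knockdown. In the Msi2 knockdown fry called the endothelial (0.0112) and blood cell markers (0.00226) higher and the neuronal genes (0.0112) lower, and in the double knockdown the endothelial (0.0105), blood cell (3.8e-04) and pancreatic markers (0.0208) higher. The blood cell markers passed by camera in the Msi2 knockdown with only the compared groups in the model (camera adjusted p = 0.0265). CD68, a lysosomal glycoprotein abundant in macrophages, was 1 of the blood cell markers that rose, from 16.0 ± 1.2 CPM in control cells to 37.1 ± 3.2, 44.1 ± 0.4 and 47.0 ± 2.0 CPM in the Msi1, Msi2 and double knockdowns.

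The second comparison asked what the Msi2 shRNA changed. The Msi2 knockdown raised SLC2A3, the glucose transporter GLUT3, from 46.0 ± 4.8 to 149.7 ± 11.8 CPM (log2 1.71 ± 0.09) and ADAMTS4, a secreted aggrecanase, from 13.9 ± 2.0 to 46.0 ± 3.5 CPM (1.75 ± 0.10). IRAK2, a kinase of interleukin-1 and Toll-like receptor signalling, rose by 1.53 ± 0.09, NES by 1.498 ± 0.09, CD68 by 1.45 ± 0.07 and the activin receptor ACVR2B by 1.35 ± 0.10. Besides MSI2 itself, genes that fell included FOS, an immediate early transcription factor, from 10.2 ± 2.4 to 2.98 ± 0.28 CPM (-1.81 ± 0.14), ABAT (-1.58 ± 0.15) and PRODH (-1.47 ± 0.10). The keratin KRT80 fell from 102 ± 7 to 40.9 ± 2.3 CPM (-1.32 ± 0.07). RN7SL2, an RNA of the signal recognition particle with near-identical copies and so an uncertain count, stood at -1.39 ± 0.22. The largest edgeR adjusted p of these genes was that of RN7SL2, 3.1e-04. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2501 genes were higher and 2044 lower, 107 and 125 of them by 2-fold or more (35 and 19 under the stricter filter, 86 and 81 with thinned libraries). The total of 4545 became 3013 without control replicate 1. DESeq2 called 2295 higher and 2035 lower.

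The NF-kB and inflammatory cytokines list rose in the Msi2 knockdown as well, with 17 of 19 genes higher, 0 lower and 2 not past the threshold (17 adjusted over the list alone; median 0.49, camera adjusted p = 1.5e-10; adjusted p = 0.0844 with an estimated correlation). CXCL8 rose by 1.09 ± 0.08, the NF-kB subunit NFKB2 by 0.61 ± 0.06 and the chemokine CXCL1 by 0.62 ± 0.07. Of the TGF-beta targets and matrix genes, 11 of 25 rose, 2 fell and 12 did not pass (14 and 4 adjusted over the list alone; camera adjusted p = 1.5e-04; adjusted p = 0.606 with an estimated correlation), with CYR61 at 0.97 ± 0.08. Of the endoplasmic reticulum chaperones, 12 of 22 rose, 1 fell and 9 did not pass (13 and 1 adjusted over the list alone; camera adjusted p = 0.001; adjusted p = 0.707 with an estimated correlation). Of the hypoxia and glycolysis genes, 9 of 30 rose, 1 fell and 20 did not pass (9 and 1 adjusted over the list alone; camera adjusted p = 0.001; adjusted p = 0.606 with an estimated correlation). Besides SLC2A3, the glycolytic genes PFKFB3 and PFKP rose by 1.06 ± 0.07 and 0.79 ± 0.08. In the ribosome biogenesis and MYC targets list 15 of 31 rose, 1 fell and 15 did not pass (16 and 1 adjusted over the list alone; camera adjusted p = 9.3e-04; adjusted p = 0.707 with an estimated correlation), MYC itself by 0.44 ± 0.06 and the RNA helicase DDX21 by 0.44 ± 0.07. Of 11 measured replication-dependent histones, 4 fell, 0 rose and 7 did not pass (4 adjusted over the list alone; median -0.53, camera adjusted p = 0.001; adjusted p = 0.273 with an estimated correlation). The median was -1.22 with thinned libraries and -0.34 without Msi2 knockdown replicate 1. HIST1H2BK went from 7.46 ± 1.5 to 2.25 ± 0.23 CPM (-1.68 ± 0.14), at a level where histone genes of similar sequence limit certainty.

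Another 7 lists were called in the Msi2 knockdown, and each of these calls was lost when some single library was left out. Each was also lost with an estimated correlation, with the values given after the last of the 7. Notch pathway genes had 10 higher and 1 lower of 18, with the receptors NOTCH1 and NOTCH3 at 0.44 ± 0.08 and 0.58 ± 0.11 (camera adjusted p = 0.0353; 0.0563, 0.053, 0.0599 and 0.0567 without control replicate 1, control replicate 3, Msi2 knockdown replicate 2 and Msi2 knockdown replicate 3; 0.114 under the stricter filter and 0.078 with thinned libraries). G2/M and mitosis genes had 17 higher and 4 lower of 38, with PRC1 at 0.52 ± 0.06 and TOP2A at -0.44 ± 0.07 (0.0226; 0.137, 0.0501 and 0.106 without control replicate 2, Msi2 knockdown replicate 1 and Msi2 knockdown replicate 3; 0.0708 under the stricter filter). Cholesterol synthesis genes had 8 higher and 2 lower of 22, with INSIG1 at 0.58 ± 0.06 (0.0223; 0.0601 without Msi2 knockdown replicate 3 and 0.0979 under the stricter filter). Apoptosis regulators had 11 higher and 3 lower of 28, with the death receptors TNFRSF10A and TNFRSF10B at 0.76 ± 0.08 and 0.59 ± 0.08 (0.0223; 0.132 without control replicate 2 and 0.0769 without Msi2 knockdown replicate 3).

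S phase and DNA replication genes had 2 higher and 8 lower of 40 in the Msi2 knockdown, with MCM4 at -0.47 ± 0.06 (camera adjusted p = 0.016; 0.106 without Msi2 knockdown replicate 2). Heat shock chaperones had 1 higher and 6 lower of 16, with CHORDC1 at -0.47 ± 0.05 (0.0223; 0.161 without Msi2 knockdown replicate 2 and 0.122 with the library trend as a covariate). Ribosomal proteins had 0 higher and 2 lower of 43, with RPL27A at -0.48 ± 0.09 (0.0329; 0.0553, 0.178, 0.0698 and 0.461 without control replicate 1, control replicate 3, Msi2 knockdown replicate 1 and Msi2 knockdown replicate 2; 0.122 with the library trend as a covariate). Adjusted over the list alone, the higher and lower counts were 10 and 1 for Notch, 20 and 4 for G2/M, 9 and 2 for cholesterol, 11 and 4 for apoptosis, 2 and 7 for S phase, 1 and 6 for heat shock and 0 and 1 for ribosomal proteins. With an estimated correlation the adjusted p of the 7 lists was 0.606, 0.751, 0.684, 0.707, 0.751, 0.751 and 0.793 in that order.

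The other 19 lists were not called in the Msi2 knockdown. Immediate early genes had 6 higher and 3 lower of 17, with NR4A1 at 1.54 ± 0.13 and FOS lower. MAPK output had 7 higher and 3 lower of 21, fatty acid synthesis 2 and 3 of 14, p53 targets 4 and 10 of 24, and the type I interferon response 4 and 3 of 34, led by IFITM1 (110.5 ± 5.1 to 234 ± 4 CPM, 1.09 ± 0.07). In the ATF4 and integrated stress response list (6 and 8 of 24) the serine and glycine synthesis genes PHGDH and SHMT2 fell by 0.67 ± 0.07 and 0.68 ± 0.06. WNT pathway genes had 7 higher and 3 lower of 16, with the secreted inhibitor SFRP1 at 0.58 ± 0.07. Musashi-linked genes had 5 higher and 5 lower of 13, stem cell and drug resistance genes 3 and 6 of 16, nuclear genes of oxidative phosphorylation 4 and 2 of 35, mesenchymal and EMT genes 3 and 3 of 13, epithelial genes 4 and 4 of 18 and chromatin regulators 3 and 3 of 26. Mitochondrially encoded genes had 0 higher and 2 lower of 13 (median -0.16, camera adjusted p = 0.129). They were called lower without control replicate 3 (adjusted p = 0.0282), without Msi2 knockdown replicate 2 (0.00197) and with the library trend as a covariate (0.0281).

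The third comparison asked what both shRNAs changed together. In the double knockdown VGF rose from 10.6 ± 1.5 to 53.1 ± 2.7 CPM (log2 2.33 ± 0.10) and CDKN1A, the cyclin-dependent kinase inhibitor p21, from 6.07 ± 0.74 to 23.5 ± 1.3 CPM (1.95 ± 0.10). DUSP5, a phosphatase of nuclear ERK, rose from 4.60 ± 0.52 to 18.6 ± 1.4 CPM (2.02 ± 0.12), ADAMTS4 by 1.98 ± 0.10, IRAK2 by 1.90 ± 0.09 and STC1 by 1.80 ± 0.12. PRODH fell to 2.08 ± 0.17 CPM (-3.26 ± 0.11), a larger change than that of MSI2. ABAT, C7orf60, TP53INP1 and NXPE3 fell by 1.98 ± 0.15, 1.85 ± 0.12, 1.71 ± 0.10 and 1.69 ± 0.11 on the log2 scale. The largest edgeR adjusted p of these genes was 8.1e-09. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3990 genes were higher and 3806 lower, 219 and 501 of them by 2-fold or more, and DESeq2 called 3885 higher and 3523 lower. The counts at 2-fold were 223 and 244 with the library trend as a covariate and 79 and 148 under the stricter filter.

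Changes in the double knockdown went with transcript length. The median log2 change was 0.23 in the fifth of genes with the shortest transcripts (207 to 2246 nt) and -0.09 in the fifth with the longest (6043 to 109224 nt), and rho across genes was -0.35, against -0.02 in the Msi1 and 0.01 in the Msi2 knockdown. Of the 7796 genes called, 4796 were called in the same direction with the library trend as a covariate and 6679 with the length correction.

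Genes of the 2 cell cycle lists were higher in the double knockdown, whose libraries lay at the low end of the library trend. With the trend as a covariate the G2/M median was 0.27, from 0.41, and the S phase median 0.17, from 0.26, with 17 S phase genes higher and 3 lower. Of 38 G2/M and mitosis genes, 30 rose, 0 fell and 8 did not pass (30 adjusted over the list alone; median 0.41, camera adjusted p = 5.9e-13; adjusted p = 0.456 with an estimated correlation). UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, rose from 101 ± 4 to 226 ± 14 CPM (1.16 ± 0.09), the mitotic activator CDC20 by 0.87 ± 0.08 and the kinesin KIF20A by 0.71 ± 0.06. Of 40 S phase and DNA replication genes, 27 rose, 1 fell and 12 did not pass (27 and 1 adjusted over the list alone; camera adjusted p = 1.3e-05; adjusted p = 0.713 with an estimated correlation). The ribonucleotide reductase subunit RRM2 rose by 1.03 ± 0.08, the helicase subunit MCM6 by 0.67 ± 0.07 and E2F1 by 0.52 ± 0.06. Of 31 ribosome biogenesis and MYC targets, 26 rose, 1 fell and 4 did not pass (26 and 1 adjusted over the list alone; camera adjusted p = 1.0e-08; adjusted p = 0.456 with an estimated correlation), with LYAR at 0.84 ± 0.08 and the spermidine synthase SRM at 0.77 ± 0.08.

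In the double knockdown the NF-kB, immediate early, MAPK output, hypoxia and TGF-beta lists were called higher. In the NF-kB and inflammatory cytokines list 17 of 19 rose, 1 fell and 1 did not pass (17 and 1 adjusted over the list alone; median 0.81, camera adjusted p = 3.8e-12; adjusted p = 0.107 with an estimated correlation). CXCL8 reached 235 ± 14 CPM (1.503 ± 0.08), CXCL1 rose by 1.01 ± 0.07 and TNFAIP3 by 0.89 ± 0.08. Of 17 immediate early genes, 14 rose, 2 fell and 1 did not pass (14 and 2 adjusted over the list alone; camera adjusted p = 4.6e-09; adjusted p = 0.317 with an estimated correlation), among them EGR3 (1.79 ± 0.09) and the phosphatase DUSP1 (1.42 ± 0.08). Of 21 MAPK output genes, 11 rose, 4 fell and 6 did not pass (11 and 4 adjusted over the list alone; camera adjusted p = 0.0021; adjusted p = 0.484 with an estimated correlation), with EGR1 at 1.04 ± 0.07 and JUN at 0.89 ± 0.07. Hypoxia and glycolysis genes had 15 of 30 higher and 4 lower (17 and 4 adjusted over the list alone; camera adjusted p = 0.0021; adjusted p = 0.552 with an estimated correlation), with SLC2A3 at 1.54 ± 0.09. TGF-beta targets and matrix genes had 10 of 25 higher and 5 lower (11 and 5 adjusted over the list alone; camera adjusted p = 0.0241; adjusted p = 0.811 with an estimated correlation), with CYR61 at 0.95 ± 0.08. With the library trend as a covariate the TGF-beta median was 0.42, from 0.18, and the hypoxia and glycolysis median 0.06, from 0.20. The TGF-beta median was also 0.34 under the stricter filter, 0.32 with the length correction and 0.06 with thinned libraries, and its call was lost without control replicate 1 (camera adjusted p = 0.0661).

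Fatty acid synthesis was the only list called lower of the 13 called in the double knockdown, with 10 of 14 genes lower and 3 higher (10 and 3 adjusted over the list alone; median -0.28, camera adjusted p = 0.0113; adjusted p = 0.456 with an estimated correlation). ACLY fell by 0.74 ± 0.06 and the desaturase SCD by 0.85 ± 0.09, while the malic enzyme ME1 rose by 0.58 ± 0.07. The fatty acid median was -0.17 with the library trend as a covariate. The other 4 called lists were higher, and each lost its call with the library trend as a covariate. Nuclear genes of oxidative phosphorylation had 24 of 35 higher and 0 lower, with COX5A at 0.59 ± 0.08 (median 0.25, camera adjusted p = 1.1e-04; with the covariate 0.06, adjusted p = 0.199). Ribosomal proteins had 23 of 43 higher and 0 lower, with RPS15 at 0.53 ± 0.08 (median 0.24, 5.5e-04; with the covariate -0.03, 0.674). Apoptosis regulators had 14 of 28 higher and 5 lower, with BAK1 at 0.94 ± 0.07 and MCL1 at 0.73 ± 0.07 (median 0.18, 0.00701; with the covariate 0.10, 0.0591). Heat shock chaperones had 11 of 16 higher and 3 lower, with HSPA4 at 0.56 ± 0.07 (median 0.23, 0.0348; with the covariate 0.02, 0.515). With the length correction the oxidative phosphorylation and ribosomal protein medians were both 0.14, and the apoptosis median was 0.33 under the stricter filter and 0.12 with thinned libraries. The heat shock call was also lost without control replicate 2 (0.0883), without double knockdown replicate 1 (0.0597), under the stricter filter (0.106) and with the length correction (0.125). Adjusted over the list alone, the higher and lower counts of these 4 lists were 26 and 0, 24 and 0, 14 and 5, and 11 and 3, and with an estimated correlation their adjusted p was 0.811, 0.811, 0.706 and 0.811.

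Of the 19 lists not called in the double knockdown, endoplasmic reticulum chaperones had 12 of 22 higher and 4 lower (median 0.26, camera adjusted p = 0.215), with HYOU1 at 0.64 ± 0.08 and SEL1L, a subunit of the degradation machinery, at -0.84 ± 0.09. This list was called higher without control replicate 2 (adjusted p = 0.0346) and with the library trend as a covariate (median 0.39, adjusted p = 2.4e-04). Cholesterol synthesis had 9 of 22 higher and 5 lower, p53 targets 9 and 9 of 24, the type I interferon response 12 and 7 of 34, ATF4 and integrated stress response 9 and 8 of 24, Notch pathway 6 and 4 of 18, WNT pathway 5 and 3 of 16, epithelial genes 7 and 6 of 18, mesenchymal and EMT genes 6 and 2 of 13, chromatin regulators 5 and 8 of 26, stem cell and drug resistance genes 4 and 4 of 16, Musashi-linked genes 3 and 6 of 13 and replication-dependent histones 0 and 4 of 11. Mitochondrially encoded genes had 0 of 13 higher and 5 lower (camera adjusted p = 0.155), and passed with only the compared groups in the model (0.036) and with the length correction (0.00643). Their median went from -0.24 to 0.08 with the library trend as a covariate, with 0 higher and 0 lower (camera adjusted p = 0.819).

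**Figure D3:**
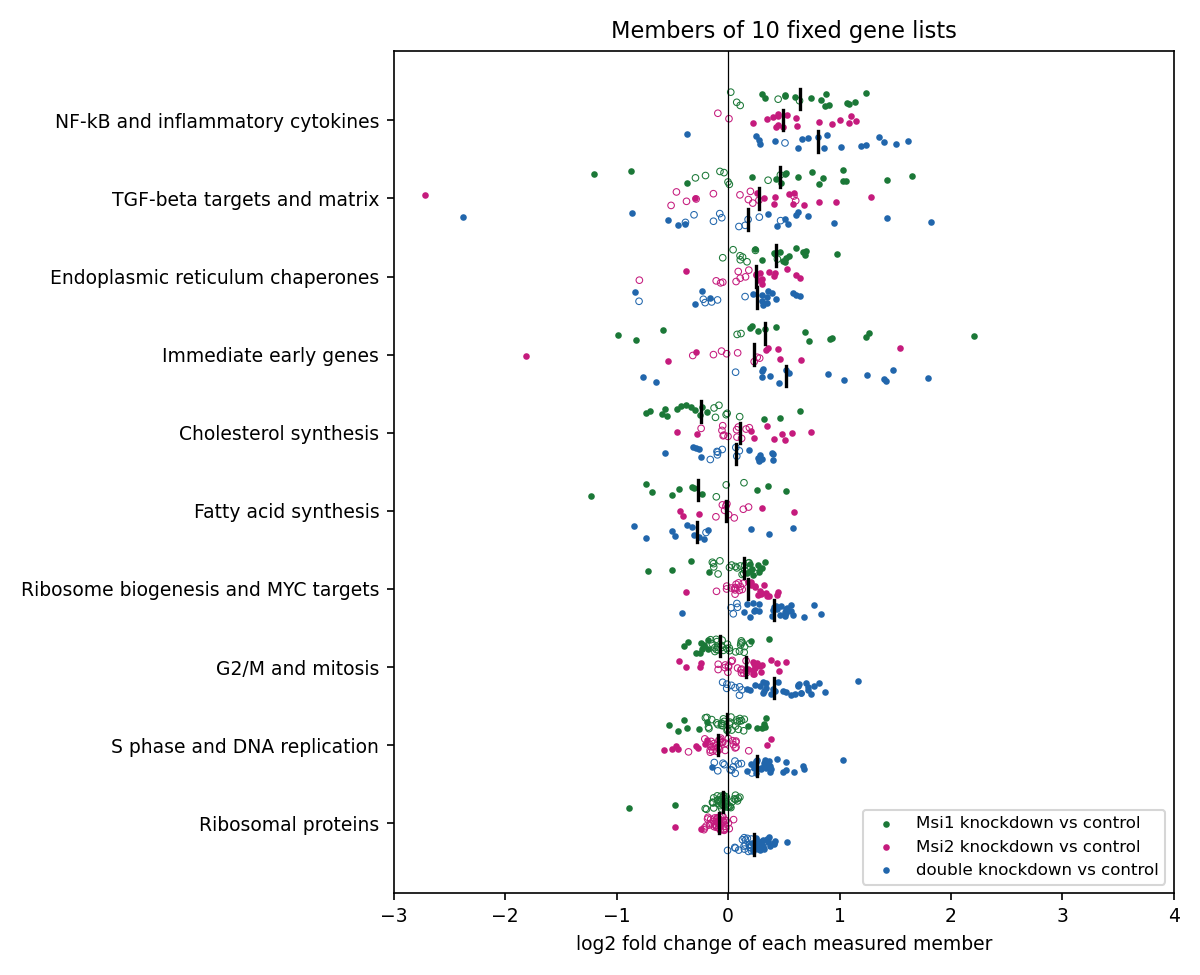
Log2 change of each measured member of 10 gene lists in the 3 comparisons with control, with filled points for genes past the adjusted p threshold and bars at the medians. The NF-kB medians are 0.64, 0.49 and 0.81, and the G2/M median is 0.41 in the double knockdown.

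Over all 32 lists camera called 7, 13 and 13 in the Msi1, Msi2 and double knockdown. With an estimated correlation 0 lists were called in each comparison (2, 2 and 2 at an unadjusted p under 0.05), and fry, which does not set a list against other genes, called 17, 15 and 19. The median, the mean and the direction of the test differed in sign for 7, 9 and 5 lists, and for 0 of the called ones.

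**Figure D4:**
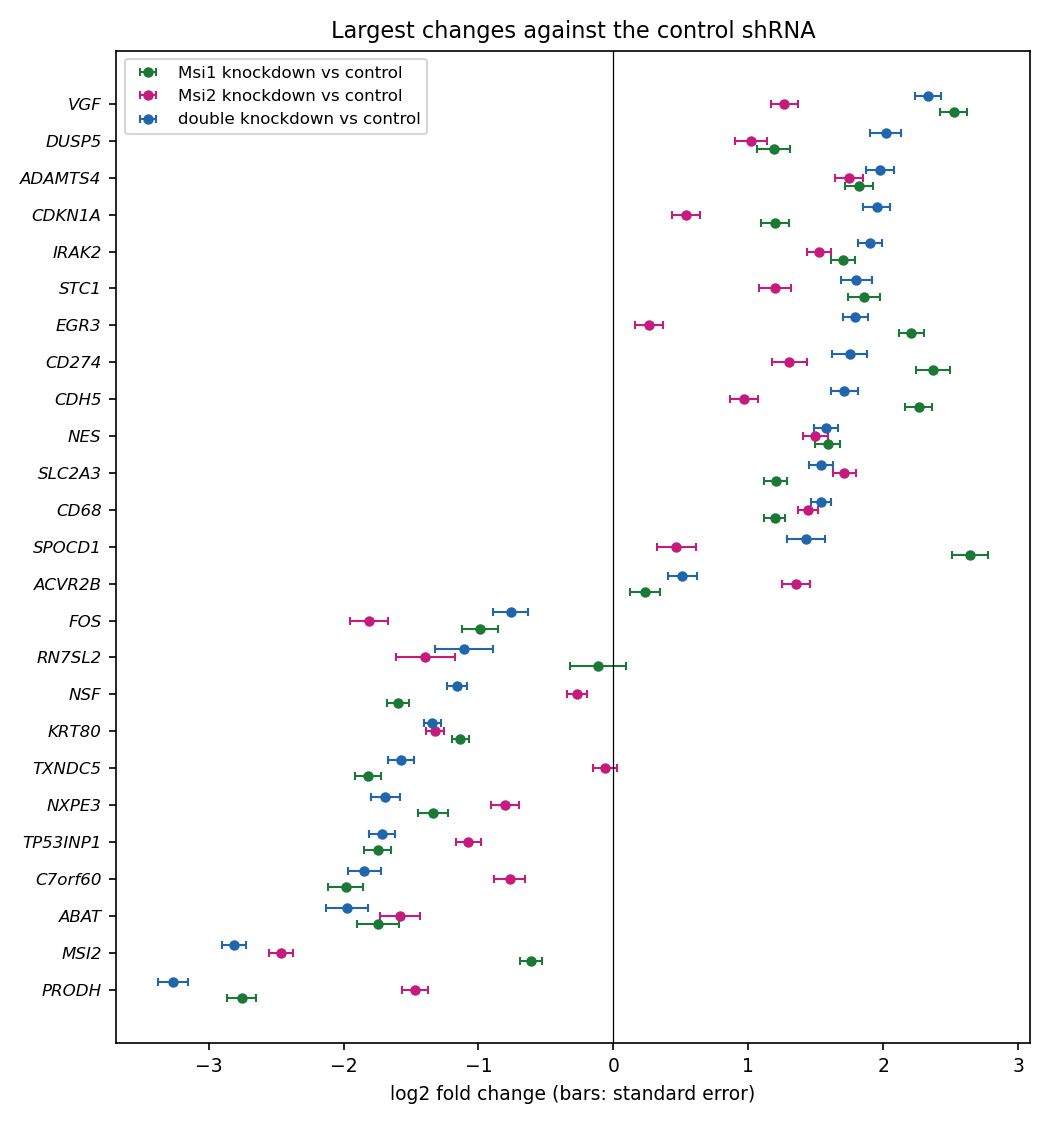
Log2 changes with standard errors of the genes named by size of change in the comparisons with control. PRODH is at -2.76, -1.47 and -3.26 and VGF at 2.52 and 2.33 in the Msi1 and double knockdowns.

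More genes changed in the same direction in both single knockdowns than independent sets would share. There were 1175 genes higher in both and 974 lower in both, where independent sets of the same sizes would share 462 and 427, and 387 went opposite ways, where independent sets would give 899. The log2 changes had a covariance of 0.0776 across genes, against 0.0234 with unchanged groups simulated against the same controls, a correlation of 0.45 against 0.57 and the same sign for 63.7% of genes against 68.4%. Part of the excess may come from the 3 shared control libraries, which are too few to split. Without control replicate 1 the shared count fell from 2149 to 1263 and the opposite count to 206, and without control replicate 2 the opposite count was 243. The opposite count was 671 with the library trend as a covariate and 244 with thinned libraries. The double knockdown shared 3145 same-direction genes with the Msi1 and 2939 with the Msi2 knockdown, with 382 and 184 opposite. Independent sets would give 736 higher and 794 lower with the Msi1, and 664 higher and 518 lower with the Msi2 knockdown. The covariances were 0.112 and 0.127, against 0.024 and 0.0235 in the simulation, and the correlations 0.49 and 0.63, against 0.57 and 0.59. Signs were the same for 62.6% and 69.1% of genes, against 68.5% and 68.8% in the simulation.

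Set against each other, the single knockdowns differed in genes of several functions. TXNDC5 was higher in the Msi2 than in the Msi1 knockdown (286 ± 11 and 84.7 ± 13.8 CPM, log2 1.76 ± 0.10), as were the mitochondrial carrier UCP2 (20.1 ± 1.7 and 5.96 ± 1.06 CPM, 1.75 ± 0.12) and the carnosine methyltransferase CARNMT1 (1.54 ± 0.07). SPOCD1, RAB7B and EGR3 were lower (-2.18 ± 0.12, -2.06 ± 0.10 and -1.95 ± 0.08). The largest edgeR adjusted p of the 6 was 2.5e-09. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 3344 genes were higher and 2837 lower, and DESeq2 called 2990 and 2813. Cholesterol synthesis separated the 2 knockdowns, with 16 of 22 genes higher in the Msi2 knockdown, 0 lower and 6 not past the threshold (17 adjusted over the list alone; median 0.38, camera adjusted p = 5.0e-07; adjusted p = 0.391 with an estimated correlation). Fatty acid synthesis (7 higher and 2 lower of 14; 8 and 2 adjusted over the list alone; adjusted p = 0.00459) and G2/M and mitosis (22 and 4 of 38; 23 and 4 alone; 0.00459) were also higher in the Msi2 knockdown by camera, and immediate early genes (4 and 11 of 17; 4 and 11 alone; 0.00239) lower. With an estimated correlation their adjusted p was 0.568, 0.822 and 0.785. The NF-kB list did not differ by the test (median -0.06, camera adjusted p = 0.194). Its members went both ways, with 3 of 19 higher and 8 lower with the library trend as a covariate (median -0.08, camera adjusted p = 0.146).

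Adding the Msi2 shRNA to the Msi1 knockdown raised UCP2 (1.36 ± 0.12), DHRS2, a short-chain dehydrogenase (1.20 ± 0.11), and the phosphatase PDXP (1.07 ± 0.11), and lowered MSI2 (-2.20 ± 0.09), with edgeR adjusted p of 7.2e-07 or less. PFN1P2, a pseudogene with an uncertain count, stood at -1.77 ± 0.35 and CCDC144A, of a family of near-identical genes, at -1.51 ± 0.34. With the library trend as a covariate, PFN1P2 was at -0.29 (edgeR adjusted p = 0.47) and CCDC144A at 0.01 (adjusted p = 0.984). There were 4486 genes higher and 3933 lower (DESeq2 4245 and 3665), 61 and 645 by 2-fold or more, and 719 were called with that covariate, 24 and 26 of them by 2-fold or more. At 2-fold there were 2 and 137 under the stricter filter, 43 and 400 with thinned libraries, and 93 higher without Msi1 knockdown replicate 1. G2/M and mitosis genes were higher, 34 of 38 with 0 lower (35 adjusted over the list alone; median 0.50, camera adjusted p = 1.2e-20; adjusted p = 0.639 with an estimated correlation), and the median was 0.28 with the covariate (camera adjusted p = 6.0e-23). Cholesterol synthesis had 12 of 22 higher and 2 lower (13 and 2 adjusted over the list alone; median 0.21, adjusted p = 3.3e-04; adjusted p = 0.639 with an estimated correlation) and a median of 0.31 with the covariate. Ribosomal proteins went from a median of 0.30 (camera adjusted p = 4.1e-07; adjusted p = 0.749 with an estimated correlation) to -0.11 with the covariate (1.0e-05).

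Adding the Msi1 shRNA to the Msi2 knockdown raised EGR3 (3.85 ± 0.06 to 11.2 ± 0.4 CPM, log2 1.53 ± 0.08), CDKN1A (1.41 ± 0.09) and DHRS2 (1.33 ± 0.11). It lowered the cholesterol exporter ABCA1 (17.6 ± 1.3 to 5.62 ± 0.50 CPM, -1.65 ± 0.12), TXNDC5 (-1.51 ± 0.09) and ATP9A (-1.42 ± 0.09), and the largest edgeR adjusted p of the 6 was 4.1e-08. There were 3413 genes higher and 3379 lower (DESeq2 3478 and 2996), and 2698 were called with the library trend as a covariate. Immediate early genes had 11 of 17 higher and 0 lower (11 adjusted over the list alone; median 0.58, camera adjusted p = 2.4e-10; adjusted p = 0.465 with an estimated correlation), with a median of 0.44 with the covariate. S phase and DNA replication genes had 36 of 40 higher and 0 lower (37 adjusted over the list alone; median 0.40, camera adjusted p = 3.3e-16; adjusted p = 0.465 with an estimated correlation), with a median of 0.24 with the covariate. Nuclear genes of oxidative phosphorylation, at a median of 0.24 (camera adjusted p = 3.5e-06; adjusted p = 0.624 with an estimated correlation), were at 0.03 with the covariate (adjusted p = 0.446).

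The last comparison asked where the double knockdown differed from the sum of the single ones. FOS fell in the Msi2 knockdown but stood at 6.20 ± 0.79 CPM in the double knockdown, 2.04 ± 0.19 above the sum on the log2 scale. DHRS2 was 1.84 ± 0.16 above the sum, and the imprinted long RNA H19 1.36 ± 0.15 above it. The complement factor CFB rose to 16.6 ± 2.0 and 14.6 ± 1.8 CPM in the single knockdowns and was 9.03 ± 1.44 CPM in the double (non-additivity -2.09 ± 0.18). CD274 and MMP14 fell short of the sum too, by -1.92 ± 0.16 and -1.87 ± 0.20. The largest edgeR adjusted p of the 6 was 1.4e-05. In all, 3192 genes lay above and 2866 below the sum, 110 and 531 by 2-fold or more (DESeq2 3157 and 2662). With the library trend as a covariate 593 were called, 183 above and 410 below, 22 and 48 of them by 2-fold or more. At 2-fold there were 24 and 215 under the stricter filter, and 344 and 310 below the sum without Msi1 knockdown replicate 2 and without Msi2 knockdown replicate 2.

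Gene lists departed from additivity in both directions, in libraries at the low end of the library trend. S phase and DNA replication genes lay above the sum, 29 of 40 with 0 below (33 adjusted over the list alone; median 0.38, camera adjusted p = 2.6e-11; adjusted p = 0.348 with an estimated correlation), as did G2/M and mitosis genes, 31 of 38 with 0 below (31 adjusted over the list alone; median 0.40, adjusted p = 2.4e-10; adjusted p = 0.348 with an estimated correlation). NF-kB and inflammatory cytokines fell short of the sum, 8 of 19 with 0 above (8 adjusted over the list alone; median -0.55, camera adjusted p = 5.8e-05; adjusted p = 0.348 with an estimated correlation), as did TGF-beta targets and matrix genes, 12 of 25 with 0 above (13 adjusted over the list alone; -0.57, 6.2e-07; adjusted p = 0.348 with an estimated correlation), and endoplasmic reticulum chaperones, 17 of 22 with 0 above (17 adjusted over the list alone; -0.50, 3.55e-09; adjusted p = 0.348 with an estimated correlation). With the library trend as a covariate these medians were 0.21, 0.13, -0.49, -0.19 and -0.19, all still called by camera (largest adjusted p = 6.2e-05). The member counts above and below the sum were then 4 and 1 for S phase, 2 and 0 for G2/M, 0 and 8 for NF-kB, 0 and 6 for TGF-beta and 0 and 5 for the chaperones. Ribosomal proteins, at 0.40 (camera adjusted p = 2.4e-10; adjusted p = 0.589 with an estimated correlation), were at -0.08 with the covariate (adjusted p = 0.0937).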

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

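The tests of the 3 patterns below against technical causes were chosen after these results were seen, and the regroupings of libraries at the end were planned. An interaction test of the difference, with edgeR and Benjamini-Hochberg adjustment, called 6058 genes, and the 3 largest rises and 3 largest falls by the naming rule are given here. The non-additive log2 changes of FOS, DHRS2 and H19 were 2.038 ± 0.19, 1.837 ± 0.16 and 1.363 ± 0.15. Those of CFB, CD274 and MMP14 were -2.09 ± 0.18, -1.921 ± 0.16 and -1.873 ± 0.20. The 6 stayed called with the library trend as a covariate, at 2.31, 1.49, 0.92, -1.44, -1.53 and -1.21 (largest adjusted p = 0.00201). Of 2634 genes that the Msi2 shRNA changed both alone and on top of the Msi1 shRNA, 781 changed in opposite directions and were also called non-additive. For the Msi1 shRNA it was 821 of 2854 genes. These 2 counts rest on comparisons of the double with a single knockdown. With the library trend as a covariate, calls there went from 8419 to 719 (Msi2 shRNA on top) and from 6792 to 2698 (Msi1 shRNA on top). Of the 8419 and 6792 genes, 561 and 2063 were called again in the same direction. The opposite changes were not counted again with the covariate.

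The double knockdown departed from the sum of the single knockdowns for 6058 genes, while its 3 libraries lay at the end of a trend that also ran within groups. The Msi1 knockdown libraries, which enter the sum, averaged 0.95 on that trend, against 0.03 in control and 0.33 in the Msi2 knockdown. With the trend in the model, 490 genes were still called in the same direction. These do not settle whether the trend was the whole cause, since a single score may take up only part of it. In simulated libraries with only a planted length trend, the covariate left a rho with length of 0.17, from 0.64, with 0 false calls either way. The trend went with much of the departure. Among all genes called non-additive the median absolute log2 change was 0.466 before and 0.161 after the trend entered the model. The median standard error went from 0.113 to 0.124. With the length correction 6168 genes were called non-additive, and 5380 of the 6058 were among them in the same direction. Most calls therefore stayed after a correction for the length of the longest transcript. Library size was argued against by 4571 genes called with all libraries thinned to the smallest total, 4306 of them among the 6058 and in the same direction. It stays open whether the combined knockdown moved the trend itself, since 3 of 3 double-knockdown libraries had scores beyond the range of the other 9. Double-knockdown cells were sorted as double-positive and the gate of the control cells is not given, so sorting cannot be told apart from the knockdown here. For genes that moved alike in all knockdowns, a shift of the 3 control libraries or a change common to the knockdown groups stays open too. Either gives a non-additive value opposite in sign to the changes against control.

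The NF-kB list was higher in each knockdown, with medians of 0.64, 0.49 and 0.81. The library trend was argued against by medians of 0.70, 0.504 and 0.70 with the trend in the model. Library size was argued against by medians of 0.63, 0.475 and 0.70 with thinned libraries. The control libraries lay below all knockdown libraries in their slope on GC content (-0.058 to -0.023 against -0.013 to 0.086). Its bearing on this list was not tested. For the rise in the single knockdowns, a shift of the 3 shared control libraries stays open. So does a response to either Musashi protein. An effect of the shRNAs beyond their targets stays open too, as 1 shRNA per target was used. The median difference between the single knockdowns was -0.0638, and each of these readings allows a small one. Members went both ways, with 3 higher and 8 lower in the Msi2 than in the Msi1 knockdown with the trend in the model. The median therefore does not decide between the readings. A control shift alone gives no difference between knockdowns, and the list did not differ between the double and the Msi1 knockdown (7 higher, 4 lower, median 0.11, camera adjusted p = 0.624) but was higher in the double than in the Msi2 knockdown (10 higher, 2 lower, median 0.27, camera adjusted p = 0.00804; adjusted p = 0.498 with an estimated correlation; median 0.16 with the trend).

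MSI2 was lower in the Msi1 knockdown. Reads shared between the 2 transcripts were argued against only if such reads were split alike in all groups, which was not tested. MSI2 lost 28.7 ± 2.2 CPM (SE) in the Msi1 knockdown, and 14.97 ± 2.36 CPM (SD) of it was left in the Msi2 knockdown. With an equal split, at most the amount left can be reads of MSI1 counted as MSI2. The library trend was argued against by a log2 change of -0.71 with the trend in the model (edgeR adjusted p = 1.1e-09). An effect of the Msi1 shRNA on MSI2 itself and a dependence of MSI2 on MSI1 stay open, as 1 shRNA per target was used and neither was tested.

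Libraries were also regrouped at random. For each comparison of 2 groups, 10 splits of the 6 libraries are too few for a share under 0.05, and only 1 of 10, the real one, gave as many genes. The real counts in the Msi1, Msi2 and double knockdown against control were 5907, 4545 and 7796, and the highest other counts 1, 0 and 0. In the Msi2 against the Msi1, the double against the Msi1 and the double against the Msi2 knockdown they were 6181, 8419 and 6792, and the highest other count was 0 each time. At an unadjusted p under 0.05 by edgeR, the highest other counts of the 6 comparisons were 3062, 1904, 821, 3634, 1986 and 1588, and the real ones 7103, 5931, 8616, 7346, 9182 and 7881, while DESeq2 was not run on the splits. Camera called as many lists in 4 of 10 splits in the Msi1 knockdown (7 lists, highest other 9), 1 of 10 in the Msi2 knockdown (13, highest other 10) and 1 of 10 in the double knockdown (13, highest other 12), so the number of called lists alone says little. Over 60 assignments of all libraries, the real one and random ones, only the real one gave as many non-additive genes (6058, highest other 696). The same held for genes shared in the same direction (2149, highest other 9) and in opposite directions (387, highest other 0). Regroupings that mix groups with different levels widen the spread within groups, which lowers the calls whatever made the groups differ. These counts therefore do not decide on chance or on a cause.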

How the results depend on the processing

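The library trend as a covariate, the length correction, the thinned libraries and the fits without mitochondrially encoded genes were chosen after the data were seen. Of the changes of named genes, 323 kept direction and side of the threshold with DESeq2, 330 with median-of-ratios size factors, 298 under the stricter filter, 315 with the trend, 324 with the length correction, 315 with thinned libraries and 307 over all left-out libraries. The number of named-gene changes with a value differed between settings, and under the stricter filter the only move was 1 change that newly passed. With the trend 9 no longer passed, 5 newly passed and 1 reversed, and over all left-out libraries 18 no longer passed and 5 newly passed. Of the list results, 96 kept theirs with median-of-ratios size factors, 84 with the trend, 83 over all left-out libraries, 68 with fry and 63 with an estimated correlation. With the trend in the model CCDC144A went from -1.51 to 0.0145 (adjusted p = 0.984) in the double against the Msi1 knockdown, and the ribosomal proteins median from 0.24 to -0.0288 (0.674) in the double knockdown against control. Values were already whole numbers, so rounding was not run as an alternative, and genes left out by the stricter filter have no value there.

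With the trend in the model the calls went from 8419 to 719 in the double against the Msi1 knockdown, from 6792 to 2698 against the Msi2 knockdown and from 6058 to 593 for non-additivity, and the genes changed in opposite directions by the single knockdowns from 387 to 671. The last count was 244 with thinned libraries. With the length correction the calls were 8447 in the double against the Msi1 knockdown, 6641 against the Msi2 knockdown and 6168 for non-additivity. Camera with an estimated correlation called 0, 0 and 0 lists in the 3 comparisons with control (2, 2 and 2 at an unadjusted p under 0.05), and fry called 17 in the Msi1 knockdown where camera called 7. The causes were not tested.

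With 1 library left out, calls ran from 4268 to 6206 in the Msi1, from 3013 to 4249 in the Msi2 and from 6477 to 7311 in the double knockdown against control, and from 4379 to 7090 for non-additivity. The lowest in the Msi2 knockdown came without control replicate 1 and the highest without Msi2 knockdown replicate 2. The MSI1 change in the Msi2 knockdown ran from 0.31 without Msi2 knockdown replicate 1 to 0.49 without Msi2 knockdown replicate 2. Genes shared by the single knockdowns were counted again only with a control library left out, not with a knockdown library left out. In the same direction they ran from 1263 without control replicate 1 to 2180 without control replicate 2. In opposite directions they ran from 206 without control replicate 1 to 272 without control replicate 3. With replicate number as a block the calls were 6336, 4970 and 8175 in the comparisons with control and 6546 for non-additivity. Equal numbers are not stated to pair samples: 10 of 18 same-number correlations were over 0.1 (range -0.534 to 0.694), and 7 of 12 libraries had their best partner under their own number.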

Other observations

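Another 4 gene lists, and the genes named from them here, were chosen after the values were seen. Complement and acute phase genes rose in the single knockdowns. C1R, a protease of the classical complement pathway, stood at 14.0 ± 1.4 CPM in control cells and 36.2 ± 4.8, 22.3 ± 0.7 and 16.9 ± 2.0 CPM in the Msi1, Msi2 and double knockdowns. LIFR, the receptor of leukemia inhibitory factor, stood at 53.9 ± 6.6, 149.7 ± 21.0, 84.5 ± 7.9 and 76.6 ± 6.0 CPM. Of 17 genes of the list, 11 rose and 0 fell in the Msi1 knockdown (camera adjusted p = 5.5e-07; adjusted p = 0.237 with an estimated correlation), 8 and 0 in the Msi2 knockdown (0.001; 0.329) and 4 and 3 in the double knockdown (0.926; 0.97). With the library trend as a covariate, 9 rose and 3 fell in the Msi1 knockdown, with a median of 0.52, from 0.69. In the double knockdown 8 rose and 2 fell with that covariate, with a median of 0.26, from 0.02 (camera adjusted p = 0.074). In the Msi2 knockdown it was 8 and 2, with a median of 0.42, from 0.46. Against the sum of the single knockdowns 13 were lower and 0 higher, with a median of -1.07 (camera adjusted p = 4.2e-13; adjusted p = 0.0614 with an estimated correlation) and -0.60 with the library trend as a covariate.

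Metallothioneins, which bind zinc and copper, rose in the Msi2 knockdown (4 of 7 higher, 0 lower, median 0.48, camera adjusted p = 0.0045; adjusted p = 0.329 with an estimated correlation) and the double knockdown (6 higher, 1 lower, median 0.84, 1.1e-04; 0.276). With the library trend as a covariate the double-knockdown median was 0.55, and the difference between the double and the Msi2 knockdown went from 0.36 to -0.005. MT2A stood at 451 ± 71 CPM in control cells and 576 ± 25, 782 ± 90 and 1081 ± 72 CPM in the Msi1, Msi2 and double knockdowns. Of 26 nuclear-retained and intron-rich transcripts, 20 fell and 0 rose in the double knockdown (median -0.68, camera adjusted p = 9.2e-07; adjusted p = 0.494 with an estimated correlation), and the median was -0.24 with the trend as a covariate. In the Msi1 knockdown 5 rose and 0 fell (median 0.27, camera adjusted p = 0.0527; 4 and 5 with a median of -0.08 with the trend), and in the Msi2 knockdown 0 rose and 6 fell (median -0.11, camera adjusted p = 0.0486; adjusted p = 0.662 with an estimated correlation; median -0.20 with the trend). NEAT1, a nuclear long RNA, stood at 587 ± 81, 591 ± 73, 405 ± 81 and 284 ± 21 CPM in the 4 groups. NRF2 targets were not called against control (camera adjusted p = 0.772, 0.413 and 0.145). LIN28A was low in each group and lower in the knockdowns than in control. It stood at 2.10 CPM in control and 0.84, 0.41 and 0.24 CPM in the Msi1, Msi2 and double knockdowns.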
